A study of Mus musculus with 61 samples.

How the data were processed

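Whole skeletal muscle of mice was profiled by bulk RNA sequencing in 61 libraries that the labels place in 22 groups. The values used were the deposited gene counts, a table of 55011 genes by 61 libraries. Per the submitters' processing notes, the authors aligned reads to mm10 with STAR 2.7.3a and counted them per gene with featureCounts, whose version is not given. Per the labels' protocols, frozen muscle was homogenised in TRIzol and each library was made from 2 ng of RNA by the ultra-low-input protocol of the Immunological Genome Project. Whether counting used strand, how reads matching several genes were treated and which annotation was used are not given in the sources used here. Values of genes with close copies (the Gbp, Tgtp, class I MHC and haemoglobin families) and of genes that overlap, such as Igtp and Irgm2, are therefore uncertain as to which member the reads came from. The counts were whole numbers, every column matched a labelled library, and 52936 of the symbols matched GENCODE vM21, from which the GRCm38 coordinates were taken.

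Each experiment was fitted alone with edgeR 4.0.16 in R 4.3.3. The fits were the 12 wild-type quadriceps libraries, the 12 wild-type tibialis anterior libraries, the 15 libraries of the acute Foxp3-DTR experiment, the 12 libraries of the training experiment, the 6 antibody libraries of trained mice and the 4 antibody libraries of aged mice. The test of a difference between the muscles used a further fit of all 24 wild-type libraries, with 13819 genes tested. Genes passed filterByExpr by group with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM factors. Comparisons used quasi-likelihood F tests on group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within a comparison. Every adjusted p of a gene in the text comes from this edgeR test unless DESeq2 is named. The fitted log2 fold changes carry edgeR's default prior count, while a prior count of 2 was used for the log2 CPM of the list tests. The standard error (SE) of a fold change is its absolute value over the square root of F. Levels are counts scaled to the library's total (CPM), given as mean ± SD. There were 19 comparisons of group pairs and 3 tests of whether a response differed between muscles or genotypes.

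Lists of genes (21 pathway lists and 13 lists of cell-type markers) were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and all alternatives except the 3 given as added. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison, and again with the estimated correlation. Of 166 list results past the threshold with the preset correlation, 5 also passed with the estimated one. These were the MHC list in tibialis anterior at day 1, the T and NK cell markers at day 7 against sedentary DTR+ mice, and the interferon-gamma, type I interferon and MHC lists in trained DTR+ against trained DTR- mice. All other list results in the text hold with the preset correlation only. The rotation test fry, which asks whether a list's own genes move one way, passed for 57 of the 166. Gene sets called in one experiment were also carried to experiments sharing no library with it.

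Genes were named by a rule with 3 parts. In each comparison it takes the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 5 CPM in either group, no overlap between the groups' libraries and an established symbol. It adds the 4 members with the smallest p of each list past the camera threshold and up to 2 called members of other lists. Foxp3, Ifng and Ppargc1a were reported whatever their p. For tests of a difference between responses it takes the 8 genes with the smallest p.

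Steps were tested on simulated counts drawn from the real genes' means and library sizes, with 200 genes changed. Of 100 genes changed by a log2 fold of 1, the test found 42 in quadriceps at day 1, 20 in sedentary acute DTR mice, 29 in trained mice and 52 in the antibody comparison. Of 100 changed by a log2 fold of 2 it found 73, 54, 80 and 93, with 4, 1, 5 and 12 false calls. These simulated libraries carried no trend on transcript length. With such a trend added to 1 group the test made 2186, 1146, 1261 and 3121 false calls. Once that trend was removed, the test made 5, 5, 5 and 10. In the aged comparison, with 2 mice per group, it found 0 of either size, so an absent call there carries no information. Libraries held 3359683 to 14445336 counts. A gene with 0 counts could have been present at up to 3 counts, which is 0.208 to 0.893 CPM depending on the library, for counting error only.

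Quadriceps and tibialis anterior of wild-type mice carry the same animal numbers, taken here to mean the same animals. The deviations of these 12 pairs of libraries from their group means correlated across genes at -0.044 to 0.075 (median 0.039). Each muscle was fitted alone so that no animal entered a fit more than once. The test of a difference between the muscles is the exception. Its main fit treated both muscles of an animal as separate samples, and the animal was a block only in an alternative. In the other experiments groups share only a replicate number. None of 56 pairs of libraries within a group was a duplicate, and the closest pair still differed by a chi-square of 4.04 per gene. P-values measure the spread between samples as labelled.

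The alternatives chosen beforehand were DESeq2 1.42.0, edgeR with RLE factors, no filter on low counts, mitochondrially encoded genes left out, only the groups compared in the fit, the replicate number as a block and leaving out each library in turn. Added after the data were seen were a fit with the trend of each library on transcript length and GC content removed, a fit with a library factor as covariate and a repeat without sedentary DTR+ replicate 2 of the training experiment. The library factor is the mean log2 level of the 100 genes that lead the main axis of spread within the 24 wild-type libraries' groups, which held 12.8% of that spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.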

Results

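Gene expression was measured in whole muscle of mice that rested, ran once or trained, with and without regulatory T cells (Tregs), the Foxp3-expressing T cells that restrain inflammation. Diphtheria toxin was given to remove Tregs in mice whose Foxp3 locus also encodes the toxin's receptor (DTR+), and DTR- mice given the toxin were the controls. Wild-type mice gave 24 libraries, 3 of quadriceps and 3 of tibialis anterior from sedentary mice and from mice 1, 2 and 7 days after exercise, with 6069064 to 8863788 counts each. The acute DTR experiment gave 15 quadriceps libraries of 4554630 to 14445336 counts, with 3 DTR- and 2 DTR+ sedentary mice, 3 of each genotype at day 1 and 2 of each at day 7. The training experiment compared 2 weeks of exercise with rest in DTR+ and DTR- mice, 3 per group, with 3359683 to 8655927 counts. Trained DTR+ mice received an antibody neutralising interferon-gamma (IFNγ) or control IgG for 1 week, 3 per group, with 4562680 to 6388765 counts. Sedentary mice of 24 months received the same antibodies, 2 per group, with 7582737 to 10359706 counts, from a muscle the labels do not name.

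Foxp3 itself lay at the limit of what whole muscle shows. It had 0 counts in 41 of 61 libraries and at most 9 counts in any. In the acute experiment the 8 DTR- libraries held 25 Foxp3 counts, 0.323 CPM when pooled, and 5 of them held any. The 7 DTR+ libraries held 2 counts, 0.0298 CPM when pooled, in 1 library (exact two-sided permutation test of the mean CPM, p = 0.0816). In the training experiment 6 DTR- libraries held 4 counts and 6 DTR+ libraries held 2 (exact two-sided permutation test, p = 1). Ifng had 0 counts in 53 of 61 libraries and at most 9, in a DTR+ library at day 7. The genotype labels were thus neither borne out nor contradicted by Foxp3, and the interferon signal had to be read from the genes it induces.

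The wild-type quadriceps libraries show how a knee extensor recovers from a bout of running. At day 1 after exercise 57 genes rose and 19 fell among 13062 tested, against sedentary mice (3 per group). Among the large rises was that of the amino acid transporter gene Slc6a19 (log2 4.93 ± 0.93, adjusted p = 0.0158), at 6.05 ± 3.11 CPM after exercise, and the cyclin gene Ccnf rose too (3.81 ± 0.70). Ankrd1, which encodes a titin-bound strain sensor, had a log2 fold change of 4.64 ± 0.36 (SE) and went from 4.53 ± 0.992 to 112 ± 48.9 CPM (edgeR, adjusted p = 9.31e-07). Csrp3, the muscle LIM protein of the Z-disc, rose from 59.7 ± 17.3 to 712 ± 73.2 CPM (log2 3.60 ± 0.26). Mustn1 (log2 3.55 ± 0.29) and the stress transcription factor Atf3 (log2 3.97 ± 0.45) rose. The small heat shock proteins Cryab (log2 2.12 ± 0.14, adjusted p = 2.1e-07), Hspb7 (2.49 ± 0.22) and Hspb1 (2.45 ± 0.24) rose. The co-chaperones Dnajb1 (2.44 ± 0.41) and Hspe1 (0.80 ± 0.16) rose as well. In the list of early response and heat shock genes 20 of 21 members were higher. Of these, 4 were called over all genes and 12 when adjusted over the list alone (camera adjusted p = 3.07e-13, adjusted p = 0.23 with an estimated correlation). The genes that fell included Ppp1r27 (log2 -0.79 ± 0.11), Lpl, the lipoprotein lipase that feeds fat to fibres (-0.52 ± 0.09), Car3 (-0.66 ± 0.12), Cpeb1 (-0.80 ± 0.14), the mitochondrially encoded mt-Co1 (-0.23 ± 0.05) and the clock gene Arntl (-1.05 ± 0.22, adjusted p = 0.0356).

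MHC genes leaned the other way in the quadriceps at day 1. All 14 MHC genes were lower, with 0 called by edgeR over all genes or over the list alone and a median log2 fold change of -0.33 (camera adjusted p = 0.000124, adjusted p = 0.306 with an estimated correlation). H2-Ab1 stood at 32.7 ± 6.7 against 49.9 ± 6.96 CPM and H2-Eb1 at 13.0 ± 1.48 against 22.4 ± 6.82 CPM. Of 32 interferon-gamma response genes 25 were lower, with a median of -0.31 (camera adjusted p = 0.00756, adjusted p = 0.23 with an estimated correlation). Ppargc1a, the coactivator of mitochondrial genes, stood at 49.1 ± 9.82 against 50.5 ± 14.8 CPM (log2 -0.02 ± 0.19).

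At day 2 the quadriceps kept part of this picture, with 34 genes higher and 5 lower. Cryab (log2 1.74 ± 0.14), Mustn1 (3.53 ± 0.29), Csrp3 (2.85 ± 0.25) and Ankrd1 (3.78 ± 0.36, adjusted p = 1.51e-05) were again raised. Mybph, a thick-filament protein of remodelling muscle, rose from 87.1 ± 11.8 to 289 ± 43 CPM (log2 1.75 ± 0.17). The phagocyte gene Cd68 rose from 5.21 ± 1.73 to 17.6 ± 3.69 CPM (log2 1.77 ± 0.36, adjusted p = 0.0418). Of macrophage markers 15 of 22 were higher with Cd68 the 1 called (camera adjusted p = 0.0321, adjusted p = 0.639 with an estimated correlation). The clock gene Per3 rose (log2 1.20 ± 0.24). Mrln, the inhibitor of the calcium pump, fell (-1.14 ± 0.16), as did Pla2g7 (-0.76 ± 0.14), Car3 (-0.60 ± 0.12) and Syne1 (-0.68 ± 0.14). The list of regeneration genes was higher in 14 of 15 members with 1 called and 3 called over the list alone (camera adjusted p = 0.000545, adjusted p = 0.491 with an estimated correlation). The early response list was higher in 15 of 21 members with 3 called (camera adjusted p = 0.0406, adjusted p = 0.647 with an estimated correlation). Lower lists were the mitochondrially encoded mRNAs, lower in 11 of 13 members (camera adjusted p = 0.00242, adjusted p = 0.491 with an estimated correlation), and fatty acid oxidation, lower in 20 of 24 (0.0321, and 0.501 with an estimated correlation), with 0 members called by edgeR in either and 2 and 3 called over the list alone.

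At day 7 the quadriceps showed raised myosins of immature fibres. Myh3, embryonic myosin, rose from 1.21 ± 0.808 to 36.3 ± 22 CPM (log2 4.91 ± 0.59, adjusted p = 0.000506) and Myh8, the perinatal form, from 1.46 ± 0.924 to 16.2 ± 10.8 CPM (log2 3.49 ± 0.64). The imprinted growth gene H19 (1.5 ± 0.2), Myh1 (0.68 ± 0.10), Sln, the fetal calcium pump regulator (2.10 ± 0.40), and the matrix gene Cilp (1.57 ± 0.25) rose. Mustn1 (1.95 ± 0.28), Csrp3 (1.44 ± 0.24) and Ankrd1 (2.14 ± 0.37) were still raised. In all 20 genes rose and 8 fell. Those that fell included Aebp1 (-0.87 ± 0.13), Gpx3 (-0.73 ± 0.13), Igfbp5 (-0.58 ± 0.10), Pink1, the kinase that marks damaged mitochondria (-0.94 ± 0.17), Gstm1 (-0.60 ± 0.12) and Car3 (-0.59 ± 0.12). In the regeneration list 12 of 15 members were higher, 3 were called and 10 were called over the list alone (median 1.23, camera adjusted p = 1.38e-09, adjusted p = 0.267 with an estimated correlation). Extracellular matrix genes were higher in 25 of 31 members with 0 called by edgeR and 3 called over the list alone (camera adjusted p = 0.00713, adjusted p = 0.939 with an estimated correlation). Postn stood at 51.5 ± 27 against 10.4 ± 5.55 CPM (adjusted p = 0.0629).

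The tibialis anterior, a dorsiflexor of the ankle, gave fewer calls in mice of the same days. At day 1, 1 gene rose and 6 fell among 12692 tested. Ppp1r27 (log2 -1.01 ± 0.12, adjusted p = 0.00121), Nmrk2, a kinase of NAD synthesis (-1.47 ± 0.19), Arntl (-1.17 ± 0.18, adjusted p = 0.0283), the matrix gene Sparc (-0.76 ± 0.12), Car3 (-0.53 ± 0.09) and H2-Ab1 (-1.27 ± 0.22, adjusted p = 0.0477) fell. Ttn rose (0.23 ± 0.04). All 14 MHC genes were lower, 1 was called and 9 were called over the list alone (median -0.76, camera adjusted p = 8.87e-11, adjusted p = 0.00969 with an estimated correlation). Matrix genes were lower in 29 of 31 members, with 1 called and 12 over the list alone (camera adjusted p = 1.71e-11, adjusted p = 0.149 with an estimated correlation). Markers of fibro-adipogenic progenitors, the matrix-making cells between fibres, were lower in 16 of 17 with 7 called over the list alone (1e-06, and 0.173 with an estimated correlation). Tendon markers were lower in 9 of 10 members and lymphatic markers in all 5. Interferon-gamma response genes were lower in 25 of 32 members and type I interferon genes in 16 of 21 (estimated-correlation adjusted p = 0.149 and 0.195). Higher lists were the clock genes, with 8 called up and 1 called down over the list alone (camera adjusted p = 0.00189, adjusted p = 0.0756 with an estimated correlation), the early response genes, higher in 15 of 19, and glycolysis, higher in 19 of 20 with a median of 0.11.

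At day 2 in the tibialis anterior 4 genes rose and 4 fell. Mybph (log2 2.85 ± 0.40), Mical2 (1.11 ± 0.17), Ide (0.86 ± 0.15) and Per3 (0.98 ± 0.17) rose. Ppp1r27 (-0.84 ± 0.12), Mylk2 (-0.47 ± 0.07), Arntl (-1.17 ± 0.18) and Fgf1 (-1.02 ± 0.17) fell, with adjusted p from 0.00947 to 0.0333. Of 9 lists past the camera threshold the clock and glycolysis lists were higher and 7 were lower, none of them with an estimated correlation (adjusted p = 0.227 for the clock list). Matrix genes were lower in 24 of 31 members, fibro-adipogenic markers in 15 of 17, tendon markers in 7 of 10, MHC genes in 11 of 14, slow fibre genes in 10 of 14, atrophy genes in 11 of 16 and mitochondrially encoded mRNAs in 12 of 13. At day 7, 2 genes passed, Nmrk2 (1.33 ± 0.19) up and the LIM protein gene Fhl1 (-0.91 ± 0.13) down (adjusted p = 0.0174 for both). Fast fibre genes were higher in 13 of 14 members with 9 called up and 1 down over the list alone, glycolysis genes in 16 of 20, interferon-gamma response genes in 25 of 32, mitochondrially encoded mRNAs in 12 of 13 and blood genes in all 6. Slow fibre genes were lower in 10 of 14, matrix genes in 27 of 31 and tendon markers in 9 of 10 (estimated-correlation adjusted p from 0.517 to 0.741).

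**Figure D1:**
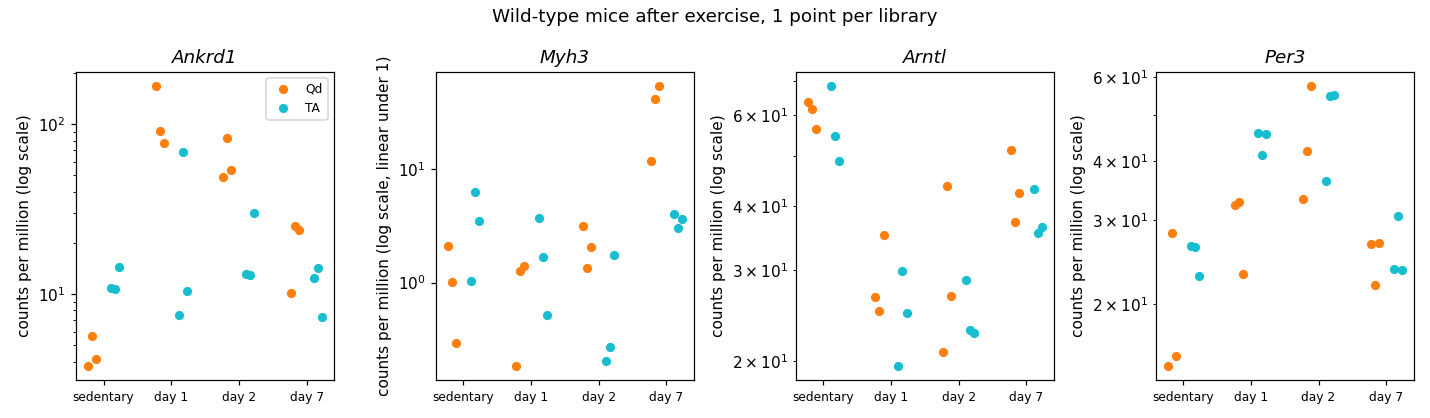
CPM on a log axis (linear under 1 for Myh3) in each wild-type library of quadriceps (Qd) and tibialis anterior (TA), by day after exercise. Ankrd1 in quadriceps went from 4.53 CPM in sedentary mice to 112 CPM at day 1, and Myh3 from 1.21 to 36.3 CPM at day 7.

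In the acute DTR experiment the comparison of resting DTR+ and DTR- mice asks what loss of Tregs does to muscle that has not run. Genes of the respiratory chain separated the groups (2 DTR+ and 3 DTR- mice). The mitochondrially encoded mt-Cytb stood at 75400 ± 8190 CPM in DTR+ and 21400 ± 5830 CPM in DTR- mice (log2 2.12 ± 0.18, adjusted p = 1.34e-07). mt-Co1 (1.32 ± 0.13), mt-Nd4 (1.37 ± 0.15) and mt-Nd1 (1.31 ± 0.15) were higher with it. So were the nuclear genes Cox7a1 (1.54 ± 0.15), Cox6a2 (1.33 ± 0.14), Cycs (1.67 ± 0.17), Ndufa12 (1.56 ± 0.16), Mrpl42 (1.76 ± 0.16) and the RNA-binding factor Ybx1 (2.26 ± 0.18). Among 14245 genes 1723 were higher and 2071 lower, but 1407 higher and 1224 lower with the trend on transcript length and GC content removed. Of 36 nuclear complex I genes 33 were called up and 1 down (median 1.00, camera adjusted p = 8.55e-18, adjusted p = 0.823 with an estimated correlation). Of 43 genes of complexes II to V 30 were called up and 3 down, of 13 mitochondrially encoded mRNAs 10 were called up, of 73 mitochondrial ribosome genes 37 up and 7 down, and of 20 mitochondrial stress genes 8 up and 2 down, each with the same adjusted p = 0.823 with an estimated correlation. Slow fibre genes were called up in 5 of 14 members (0.856 with an estimated correlation). Mitochondrial genes took 21.4 to 23.5% of counts in DTR+ and 7.9 to 12% in DTR- sedentary libraries. In the same libraries 14701 to 14745 against 16508 to 16799 genes were detected.

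Among the genes lower in the same resting DTR+ mice was Atp2a1. This calcium pump of fast fibres stood at 5850 ± 469 against 38200 ± 14300 CPM (log2 -2.39 ± 0.24, adjusted p = 8.29e-07). The insulin-responsive glucose transporter Slc2a4 (-1.52 ± 0.16), the glycolytic genes Pkm (-1.25 ± 0.15) and Pfkm (-1.18 ± 0.15), the glycogen synthase Gys1 (-1.02 ± 0.14) and the fat oxidation genes Hadha (-1.30 ± 0.15) and Acads (-2.05 ± 0.24) were lower. The glycolysis list had 12 of 20 members called down and 1 up (camera adjusted p = 0.035, adjusted p = 0.856 with an estimated correlation). The immediate early genes Nr4a1 (-2.45 ± 0.28) and Jun (-1.59 ± 0.29), the growth brake Mstn (-1.59 ± 0.21) and Myog (-2.04 ± 0.38) were lower. Myf6 was higher (1.35 ± 0.17). Of immune genes the complement gene C1qa (-1.97 ± 0.33) and Cd74 (-1.30 ± 0.31) were lower, while the interferon-induced genes Gbp4 (2.54 ± 0.50), Tgtp2 (3.10 ± 0.67), Rtp4 (1.63 ± 0.41) and Ly6a (1.09 ± 0.24) were higher. B2m was higher (0.84 ± 0.30) and Des lower (-0.88 ± 0.16), but with the trend on transcript length and GC content removed both turned to the other side of 0 (-0.51 and 0.10). Ppargc1a stood at 15.8 ± 0.154 against 29.8 ± 5.9 CPM (log2 -0.60 ± 0.23, adjusted p = 0.0542).

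**Figure D2:**
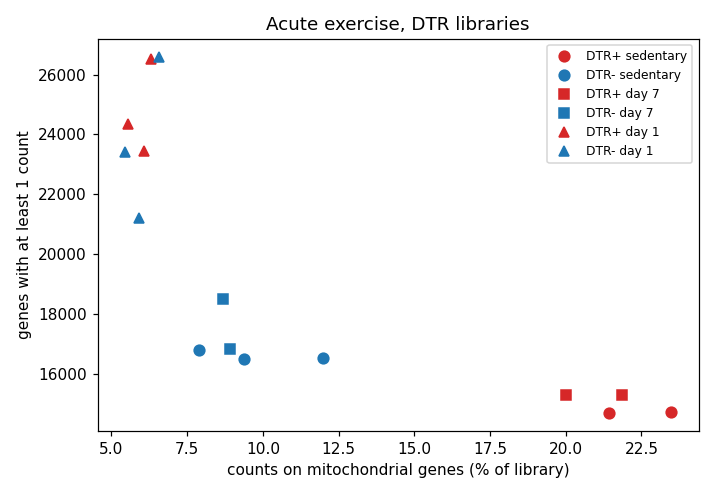
Genes with at least 1 count against the percent of counts on mitochondrial genes in each of the 15 libraries of the acute DTR experiment. The sedentary and day 7 DTR+ libraries lie at 20 to 23.5% with 14701 to 15306 genes, the day 1 libraries of both genotypes at 5.44 to 6.56% with 21211 to 26596 genes.

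The same contrast at day 1 after exercise, when damage is being cleared, gave 0 called genes by edgeR and 0 by DESeq2 (3 mice per group), with 280 genes at an unadjusted p under 0.05. Interferon-induced genes leaned upward, with 29 of 41 interferon-gamma response genes higher (median 0.19, camera adjusted p = 2e-04, adjusted p = 0.796 with an estimated correlation) and 22 of 28 type I interferon genes higher (2e-04). Rsad2, an antiviral enzyme, stood at 14.1 ± 1.1 against 6.42 ± 3.35 CPM (log2 1.17 ± 0.40) and Gbp4 at 39.3 ± 2.74 against 18.5 ± 16.2 CPM (1.11 ± 0.41). Early response genes leaned downward in 17 of 20 members (median -0.36), matrix genes in 26 of 32, fibro-adipogenic markers in 14 of 17, complex I genes in 35 of 36 (median -0.09), complexes II to V in 38 of 43 and mitochondrial ribosome genes in 56 of 73, all at an adjusted p of 0.796 with an estimated correlation. With simulated changes of a log2 fold of 2 this comparison found 66 of 100 genes.

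At day 7 after exercise many interferon-induced genes were higher in DTR+ than DTR- muscle (2 mice per group). The guanylate-binding protein gene Gbp6 stood at 119 ± 136 against 0.333 ± 0.16 CPM (log2 8.56 ± 0.89, adjusted p = 1.8e-06). The interferon-inducible GTPases followed, Igtp at 1230 ± 1380 against 17.2 ± 6.68 CPM (6.40 ± 0.73) and Iigp1 with 6.65 ± 0.88. Both DTR+ mice exceeded both controls, and they differed widely from each other. The immunoproteasome genes Psmb8 (3.74 ± 0.40) and Psme2 (2.73 ± 0.34), the T-cell attractant Cxcl9 (6.51 ± 0.99), the MHC genes H2-Ab1 (2.07 ± 0.25), H2-Eb1 (2.22 ± 0.30) and H2-T23 (2.90 ± 0.41) with B2m (2.46 ± 0.35), and Ifit3 (4.75 ± 0.67) and Bst2 (2.20 ± 0.38) were higher. Of 41 interferon-gamma response genes 35 were called up and 1 down (median 3.65, the same with the 2 members at 0 in a group set to their bound, camera adjusted p = 5.99e-17, adjusted p = 0.413 with an estimated correlation). Of 15 MHC genes 12 were called up (median 2.12), and of 28 type I interferon genes 10 (adjusted p = 0.413 and 0.424 with an estimated correlation). In all 1613 genes were higher and 1995 lower, around a median of all genes of -0.10. The balance turned with the trend on transcript length and GC content removed (1309 higher and 1245 lower) and with only these groups in the fit (1121 and 907).

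Markers of T and NK cells and of macrophages were among the genes higher at day 7 in DTR+ mice, and a few neutrophil markers among those lower. The kinase of T cells Lck stood at 8.16 ± 0.217 against 0.329 ± 0.466 CPM (log2 5.20 ± 1.15, adjusted p = 0.0023), and the cytotoxic granule gene Nkg7 at 14.6 ± 15.2 against 0.333 ± 0.16 CPM (5.58 ± 1.28). Cd3d and Cd2 stood at 5.49 ± 6.03 and 4.6 ± 3.05 CPM with 0 counts in both DTR- libraries. Of 16 T and NK cell markers 9 were called up and 12 over the list alone (median 4.85, or 3.76 with the 6 members at 0 in a group at their bound, adjusted p = 0.373 with an estimated correlation). Macrophage markers were called up in 11 of 26 members and down in 1, with Fcer1g (2.14 ± 0.38), Lyz2 (1.48 ± 0.29) and Ctss (2.30 ± 0.49) among them. The chemokine list had 7 of 15 up and 1 down, with Ccl7 (4.98 ± 0.77), Ccl8 (4.19 ± 0.62) and Ccl6 (2.58 ± 0.36). Of 10 neutrophil markers 4 were called down, among them S100a8 at 1.91 ± 2.07 against 25.6 ± 30.2 CPM (-3.44 ± 1.02), with a spread between the DTR- mice as large as their mean. With the replicate number as block none of the 4 was called (adjusted p = 0.288 for S100a8). Blood genes were called up in 4 of 8 members. The estimated-correlation adjusted p was 0.424 to 0.432 for these 4 lists.

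Metabolic genes were among those called at day 7. Slc2a4 (log2 -1.93 ± 0.17), Atp2a1 (-2.25 ± 0.25), Ppargc1a (-1.38 ± 0.25, adjusted p = 0.000428; 10.2 ± 0.411 against 32.1 ± 1.99 CPM), its partner Esrra (-1.45 ± 0.25) and their target Perm1 (-1.81 ± 0.24) were lower in DTR+ mice, and mt-Cytb (2.39 ± 0.21) was higher. Complex I had 33 of 36 genes called up (adjusted p = 0.424 with an estimated correlation), complexes II to V 30 of 43 up and 2 down, mitochondrially encoded mRNAs 10 of 13 up, mitochondrial ribosome genes 36 of 73 up and 7 down, and mitochondrial stress genes 9 of 20 up and 1 down. Glycolysis had 10 of 20 called down and 1 up. Matrix genes had 11 of 32 called down, Bgn (-1.63 ± 0.29) and Col6a2 (-1.40 ± 0.28) among them (camera adjusted p = 0.0109, adjusted p = 0.618 with an estimated correlation). Mitochondrial genes took 20 to 21.8% of counts in DTR+ and 8.7 to 8.92% in DTR- libraries at day 7, and 15300 to 15306 against 16843 to 18494 genes were detected.

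The responses to exercise within each genotype rest on the same libraries. In DTR- mice at day 1 against rest (3 per group), Ankrd1 went from 6.14 ± 1.47 to 178 ± 48.1 CPM (log2 4.59 ± 0.38, adjusted p = 1.58e-07), Csrp3 had a log2 fold change of 4 ± 0.26 and Mustn1 one of 3.77 ± 0.29. Hspb1 (3.04 ± 0.29), Cryab (1.65 ± 0.21), Atf3 (4.68 ± 0.51), the myogenic factor Runx1 (3.30 ± 0.75), Ccl2 (2.06 ± 0.62) and the clock genes Per1 (3.26 ± 0.59) and Nr1d2 (1.53 ± 0.19) rose. Nmrk2 (-2.83 ± 0.34), Igfbp5 (-1.70 ± 0.21), mt-Nd1 (-1.16 ± 0.14), Pgam2 (-1.53 ± 0.19) and Ndufa13 (-1.07 ± 0.14) fell. Of the 57 genes that rose in wild-type quadriceps at day 1, 56 were higher here and 41 were called (camera p = 5.2e-25, p = 0.0165 with an estimated correlation). Early response genes had 10 of 20 called up and 12 over the list alone. Complex I had 35 of 36 called down (median -0.73), complexes II to V 32 of 43, mitochondrially encoded mRNAs 8 of 13, mitochondrial ribosome genes 37 of 73 and fast fibre genes 7 of 14 (estimated-correlation adjusted p = 0.324, and 0.414 for the mRNAs). Fatty acid oxidation had 11 called down and 3 up, the citrate cycle 8 down and 1 up and glycolysis 8 down and 2 up. In all 1163 genes rose and 1174 fell. The day 1 libraries gave mitochondrial genes 5.44 to 6.56% of counts and detected 21211 to 26596 genes. At rest these were 7.9 to 12% and 16508 to 16799. The log2 level of short against long transcripts was 0.0578 to 0.221 at day 1 and 0.784 to 1.12 at rest. Exercise and library content therefore cannot be separated for the lists that fell.

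In DTR+ mice at day 1 against rest 3456 genes were higher and 2577 lower (3 against 2 mice), around a median of all genes of 0.28. Csrp3 (log2 3.65 ± 0.30), Ankrd1 (4.74 ± 0.47), Hspb1 (3.26 ± 0.34), Nr4a1 (3.22 ± 0.29), Atp2a1 (2.96 ± 0.24), Slc2a4 (1.77 ± 0.16) and Ppargc1a (0.64 ± 0.23, adjusted p = 0.0274) were higher. In contrast mt-Cytb (-3.55 ± 0.19), Mrpl42 (-2.85 ± 0.16), Cox7a1 (-2.66 ± 0.15) and Ybx1 (-3.27 ± 0.19) were lower. Complex I had 35 of 36 genes called down (median -1.79, adjusted p = 0.347 with an estimated correlation), complexes II to V 37 down and 1 up, mitochondrially encoded mRNAs 10 down and 1 up, mitochondrial ribosome genes 54 down and 5 up, mitochondrial stress genes 13 down and 4 up and fast fibre genes 8 down and 3 up. The test of whether the recovery responses differ by genotype called 2610 genes, led by the pyruvate dehydrogenase kinase Pdk2 (adjusted p = 3.39e-07), Arfgap2, Mylk2, the calcium channel Cacna1s, the lactate carrier Slc16a3, Calcoco1, Dctn1 and Itga7 (1.37e-06). The day 1 libraries of both genotypes detected 21211 to 26596 genes and gave mitochondrial genes 5.44 to 6.56% of counts, unlike the libraries of the other days.

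At day 7 against rest DTR- mice showed 1 called gene, S100a8, the calcium-binding protein of neutrophils, at 25.6 ± 30.2 against 0.0775 ± 0.0675 CPM (log2 8.06 ± 1.22, adjusted p = 0.0263). Its partner S100a9 stood at 19.8 ± 25.1 against 0.0726 ± 0.126 CPM (adjusted p = 0.0618), and 9 of 10 neutrophil markers were higher with 6 called over the list alone (camera adjusted p = 1.6e-09, adjusted p = 0.356 with an estimated correlation). With DESeq2 63 genes were called, S100a8 not among them. With the replicate number as block edgeR did not call S100a8 either. Slow fibre genes were higher in 9 of 14 members, and complex I in all 36 (median -0.27), complexes II to V in 38 of 43, mitochondrial ribosome genes in 62 of 73, fatty acid oxidation in 21 of 24 and glycolysis in 14 of 20 were lower, at an adjusted p of 0.814 with an estimated correlation.

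In DTR+ mice 90 genes rose and 54 fell at day 7 against rest (2 mice per group). Igtp rose from 26.9 ± 8.87 to 1230 ± 1380 CPM (log2 5.39 ± 0.69, adjusted p = 0.000297), and Gbp6 (5.64 ± 0.70), H2-Ab1 (1.97 ± 0.25), H2-Aa (2.26 ± 0.29), H2-Eb1 (1.92 ± 0.30), H2-T23 (2.41 ± 0.39), Ifit3 (2.56 ± 0.58), Ccl8 (2.45 ± 0.56) and Zbp1 (6.55 ± 1.32) rose with it. Lck stood at 8.16 ± 0.217 CPM and Nkg7 at 14.6 ± 15.2 CPM with 0 counts in both resting libraries. Csrp3 (1.83 ± 0.30), Ankrd1 (2.25 ± 0.49) and Sln (1.81 ± 0.36) rose. Col1a1 (-1.42 ± 0.33), Col6a1 (-0.81 ± 0.19), Dusp1 (-1.18 ± 0.28) and Prx (-3.60 ± 0.80) fell. All 41 interferon-gamma response genes were higher, 18 were called and 34 were called over the list alone (median 2.35, adjusted p = 0.235 with an estimated correlation), as were all 15 MHC genes with 9 called and 14 over the list alone (0.233). Of 16 T and NK cell markers 15 were higher, 3 were called and 13 over the list alone (camera adjusted p = 1.24e-13, adjusted p = 0.0445 with an estimated correlation). Matrix genes were lower in 29 of 32 members with 2 called and 9 over the list alone, fibro-adipogenic markers in 13 of 17, tendon markers in 10 of 12, glycolysis in 18 of 20, complex I in all 36, complexes II to V in 40 of 43 and mitochondrial ribosome genes in 61 of 73. Type I interferon genes were higher in 19 of 28, chemokines in 11 of 15, macrophage markers in 23 of 26 and blood genes in 7 of 8 (estimated-correlation adjusted p from 0.466 to 0.527). The count was 346 without DTR+ day 7 replicate 2, 76 without replicate 3 and 1 with only these 2 groups in the fit.

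The training experiment asks whether 2 weeks of exercise remodel muscle in mice given the toxin to deplete Tregs. In DTR- mice Fhl1, Mb, Myh1 and Myom3 rose with training (3 per group). Fhl1 rose from 831 ± 9.37 to 2530 ± 148 CPM (log2 1.55 ± 0.18, adjusted p = 0.00101), myoglobin Mb from 752 ± 136 to 1820 ± 120 CPM (1.21 ± 0.18), Myh1 from 2750 ± 193 to 7010 ± 1570 CPM (1.29 ± 0.18) and Myom3, an M-band protein of intermediate fibres, from 32.4 ± 3.85 to 101 ± 18.5 CPM (1.59 ± 0.24). The lipid synthesis genes Acly (1.64 ± 0.28) and Mid1ip1 (1.61 ± 0.24), Mustn1 (2.10 ± 0.27), Hspb7 (1.63 ± 0.27) and Uchl1 (2.12 ± 0.40) rose. The calcineurin inhibitor Rcan1 (-1.25 ± 0.23) and Tigar (-0.93 ± 0.18) fell. In all 10 genes rose and 3 fell among 12579, but edgeR called 0 genes down with the replicate number as block, with the library factor as a covariate or without any 1 of the DTR- mice. Macrophage markers were higher in 22 of 24 members with 5 called over the list alone (median 0.59, camera adjusted p = 3.03e-08, adjusted p = 0.186 with an estimated correlation), endothelial markers in 18 of 20 with 3 over the list alone (0.000245, and 0.186 with an estimated correlation) and dendritic and mast cell markers in 7 of 9. Complex I was higher in 34 of 36 members, complexes II to V in 41 of 43, the citrate cycle in 17 of 19, fatty acid oxidation in 21 of 24, MHC genes in 12 of 14, type I interferon genes in 19 of 26 and slow fibre genes in 9 of 14. Fast fibre genes were lower in 13 of 14 members, tendon markers in 9 of 10, nerve markers in 10 of 11, early response genes in 15 of 17 and glycolysis in 16 of 20 (estimated-correlation adjusted p from 0.096 to 0.732).

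In DTR+ mice training gave 123 genes up and 155 down (3 per group). Mb (log2 1.62 ± 0.18), Myh1 (1.36 ± 0.18), Myh2 (1.66 ± 0.25) and Casq2, the calcium store of slow fibres (1.47 ± 0.25), rose. Myh4, the fastest myosin, fell (-0.80 ± 0.14). Of genes that burn fat and carbohydrate the following rose, Cd36 (0.89 ± 0.17), Decr1 (0.91 ± 0.16), Hadha (0.70 ± 0.17), Etfdh (0.91 ± 0.19), Cs (0.57 ± 0.14), Dlst (0.71 ± 0.16) and Hk2 (0.83 ± 0.18). The GTPase gene Irgm2 went from 28.6 ± 7.18 to 379 ± 250 CPM (3.68 ± 0.37, adjusted p = 2.55e-05), with Iigp1 (3.49 ± 0.39), Igtp (3.51 ± 0.39), Gbp10 (5.68 ± 0.62), Rsad2 (2.7 ± 0.33), Ido1 (4.78 ± 0.83), Cxcl9 (4.01 ± 0.70), Cxcl10 (4.54 ± 1.06) and B2m (1.02 ± 0.21). The ubiquitin ligase gene Rnf187 (-2.74 ± 0.39), Upf3a (-2.82 ± 0.45), Cited4 (-3.39 ± 0.64), Car3 (-1.03 ± 0.20), C1qc (-1.99 ± 0.41), Tnc (-1.53 ± 0.33) and Col5a1 (-1.03 ± 0.25) fell. Ppargc1a had a log2 fold change of 0.88 ± 0.25 (adjusted p = 0.0738).

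By list, trained DTR+ mice had 26 of 40 interferon-gamma response genes called up against sedentary DTR+ mice, 36 over the list alone (median 1.67, camera adjusted p = 6.29e-35, adjusted p = 0.139 with an estimated correlation), 4 of 26 type I interferon genes and 6 of 14 MHC genes. All 19 citrate cycle genes were higher, 2 were called and 8 over the list alone (adjusted p = 0.299 with an estimated correlation), and fatty acid oxidation had 5 of 24 called and 12 over the list alone (0.299). Complexes II to V were higher in 35 of 43 members, complex I in 23 of 36, mitochondrially encoded mRNAs in 10 of 11, mitochondrial ribosome genes in 40 of 73, slow fibre genes in 9 of 14 with 3 called, regeneration genes in 10 of 13, cell cycle genes in 13 of 17 and macrophage markers in 19 of 24. Fast fibre genes were lower in 13 of 14, matrix genes in 24 of 31 with 2 called and tendon markers in 9 of 10 (estimated-correlation adjusted p from 0.139 to 0.745). The factor score was 0.63 ± 0.26 in sedentary and -0.79 ± 0.41 in trained DTR+ libraries. With the library factor as a covariate 3 genes were called, 2 of them among the 278, and complex I (-0.24), complexes II to V (-0.15), mitochondrially encoded mRNAs (-0.58), mitochondrial ribosome genes (-0.22) and matrix genes (0.20) lay on the other side of 0. The count was 849 without sedentary DTR+ replicate 2, whose group spanned -0.93 to 0.80 in the log2 level of short against long transcripts, and 53 without trained DTR+ replicate 2.

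At rest, DTR+ mice of the training experiment had 6 called genes against DTR- mice, all higher (3 per group). Gbp4 stood at 55.9 ± 24.6 against 13.1 ± 2.67 CPM (log2 2.10 ± 0.31, adjusted p = 0.0135), and the checkpoint ligand Cd274 (2.94 ± 0.44), Cd74 (1.34 ± 0.21), Tgtp2 (2.43 ± 0.38) and Gbp3 (2.18 ± 0.36) rose. With only these 2 groups in the fit, or without any 1 of the sedentary DTR- mice, edgeR called 0 genes. Of 40 interferon-gamma response genes 38 were higher, 4 called and 21 called over the list alone (median 1.42, or 1.38 with 2 members at their bound, camera adjusted p = 1.64e-24, adjusted p = 0.119 with an estimated correlation). All 14 MHC genes were higher with 1 called and 11 over the list alone (median 0.99, adjusted p = 0.119). Macrophage markers were higher in 22 of 24 members, atrophy genes in 15 of 16, type I interferon genes in 24 of 26 and chemokines in 9 of 12, and tendon markers were lower in 9 of 10 (estimated-correlation adjusted p from 0.119 to 0.196).

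After training 78 genes were higher and 34 lower in DTR+ than DTR- mice, and interferon-induced genes were among those higher (3 per group). The balance was 44 and 3 without trained DTR+ replicate 2, 90 and 149 without replicate 3, and 112 and 148 without a filter on low counts. Iigp1, on chromosome 18 from 60376027 to 60392634, stood at 526 ± 371 against 12.4 ± 3.5 CPM (log2 5.46 ± 0.44, adjusted p = 1.53e-06). Irgm2 (4.74 ± 0.39), Igtp (4.94 ± 0.42), Gbp4 (3.50 ± 0.32), on chromosome 5 from 105115767 to 105139586, and Gbp10 (5.70 ± 0.60) rose. So did Ido1, an enzyme that breaks down tryptophan (7.34 ± 1.04), and the antiviral genes Ifit3 (2.61 ± 0.34), Rsad2 (2.43 ± 0.32), Oasl2 (1.98 ± 0.35) and Rtp4 (1.77 ± 0.27). B2m, on chromosome 2 from 122147686 to 122153083, stood at 410 ± 102 against 150 ± 18.1 CPM (1.5 ± 0.21), with H2-K1 (1.42 ± 0.22), H2-Q7 (3.30 ± 0.37) and H2-T23 (2.59 ± 0.42). Ly6a (1.53 ± 0.23), Ccl8 (2.98 ± 0.51), Ctss (1.43 ± 0.31) and the cell cycle inhibitor Cdkn1a (1.56 ± 0.32) were higher too. All 40 interferon-gamma response genes were higher, 33 called and 38 called over the list alone (median 3.58, camera adjusted p = 4.93e-81, adjusted p = 0.0112 with an estimated correlation). All 26 type I interferon genes were higher with 8 called and 20 over the list alone (median 1.62, adjusted p = 0.0239 with an estimated correlation), and all 14 MHC genes with 8 called and 13 over the list alone (median 1.34, 0.0335).

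Among the 34 genes lower in trained DTR+ mice, Rnf187, on chromosome 11 from 58932288 to 58938916, stood at 25.2 ± 11.6 against 121 ± 76.2 CPM (log2 -2.20 ± 0.39, adjusted p = 0.00413), and Upf3a (-2.41 ± 0.45), Tsen34 (-1.84 ± 0.29), Phlda3 (-1.75 ± 0.34), Fance (-1.85 ± 0.37), Rflnb (-1.81 ± 0.41), Sfrp2 (-1.88 ± 0.43) and Trp53rka (-1.71 ± 0.40) fell. Of the 34 genes lower here 20 belong to the 100 genes of the library factor, which scored -0.79 ± 0.41 in trained DTR+, 0.32 ± 0.59 in trained DTR- and 0.63 ± 0.26 in sedentary DTR+ libraries. With this factor as a covariate 10 genes were called, all higher, and fatty acid oxidation lay on the other side of 0 (-0.01). Matrix genes were lower in 29 of 31 members, with 0 called by edgeR and 4 over the list alone (median -0.43, camera adjusted p = 4.07e-08, adjusted p = 0.3 with an estimated correlation), and tendon markers in 9 of 10. Fatty acid oxidation genes were higher in 21 of 24 members with 0 called by edgeR, macrophage markers in 20 of 24 with 1 called, chemokines in 10 of 12 with 1 called and atrophy genes in 12 of 16 with 1 called (estimated-correlation adjusted p from 0.178 to 0.544). Ppargc1a stood at 57.4 ± 5.91 against 51.4 ± 9.88 CPM (0.22 ± 0.25, adjusted p = 0.977).

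**Figure D3:**
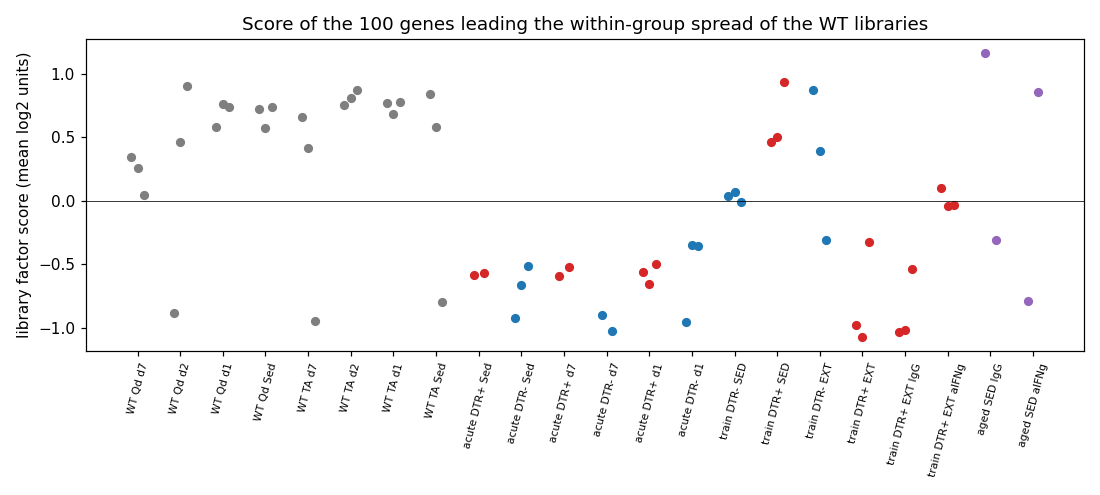
Mean log2 score of the 100 genes of the library factor in each of the 61 libraries. Within wild-type groups single libraries lie near -0.88 (quadriceps day 2), -0.95 (tibialis anterior day 7) and -0.80 (tibialis anterior sedentary) while others of their group reach 0.90, 0.66 and 0.84. The sedentary library belongs to the reference group of each tibialis anterior comparison.

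The direct test of whether training acts differently in the 2 genotypes called 34 genes, where the log2 response in DTR+ minus that in DTR- mice was positive for 9 and negative for 25. Irgm2 (log2 difference 4.13 ± 0.51, adjusted p = 0.00181), Igtp (3.52 ± 0.55), Irgm1 (2.97 ± 0.49) and Iigp1 (3.33 ± 0.56) had positive differences. Phlda3 (-3.30 ± 0.47), Rnf187 (-3.25 ± 0.53), Timm29 (-2.33 ± 0.37) and Lamp1 (-2.07 ± 0.35) had negative ones, and these 4 fell with training in DTR+ mice. Interferon-gamma response genes had 7 of 40 members called and 23 over the list alone (median 1.65, camera adjusted p = 1.54e-29, adjusted p = 0.236 with an estimated correlation). Type I interferon genes were positive in 22 of 26 members, MHC genes in 10 of 14, the citrate cycle in all 19 and fatty acid oxidation in 21 of 24, and matrix genes were negative in 25 of 31 (0.64 to 0.764 with an estimated correlation). With the library factor as a covariate MHC genes (-0.21), the citrate cycle (-0.11), fatty acid oxidation (-0.18) and matrix genes (0.35) lay on the other side of 0 and 1 gene was called, not among the 34. The count was 2 without trained DTR- replicate 1.

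Neutralising IFNγ in trained DTR+ mice asks how much of this gap depends on the cytokine. Against IgG, 84 genes fell and 74 rose among 11742 (3 mice per group). Without IgG replicate 3 the numbers were 108 and 274, and without IgG replicate 2 56 and 17. Gbp4 went from 137 ± 29.5 to 8.11 ± 1.41 CPM (log2 -4.07 ± 0.18, adjusted p = 1.89e-08) and Cd274 from 51.1 ± 10.1 to 3.62 ± 0.357 CPM (-3.81 ± 0.21). Gbp2 (-3.28 ± 0.20), Iigp1 (-3.88 ± 0.26), Tgtp2 (-3.74 ± 0.28), Gbp10 (-4.15 ± 0.63) and Ido1 (-3.88 ± 0.70) fell. So did H2-K1 (-1.12 ± 0.10), H2-D1 (-1.11 ± 0.10), B2m (-0.99 ± 0.09) and Ly6a (-0.95 ± 0.10), and genes often induced by type I interferon such as Irf7 (-1.45 ± 0.17), Ifit2 (-1.72 ± 0.23), Rsad2 (-1.29 ± 0.19) and Bst2 (-1.05 ± 0.17). The slow fibre genes Myh7 (-1.18 ± 0.24) and Tnni1 (-1.02 ± 0.18), Plin4 (-0.74 ± 0.14) and C1qb (-0.80 ± 0.18) fell as well. All 36 interferon-gamma response genes were lower, 30 called and 33 called over the list alone (median -2.21, camera adjusted p = 2.08e-54, adjusted p = 0.139 with an estimated correlation). All 14 MHC genes were lower with 9 called and 13 over the list alone, and 25 of 26 type I interferon genes with 8 called and 15 over the list alone (0.184 with an estimated correlation for both).

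Of 75 genes higher in trained DTR+ than DTR- mice and tested with the antibody, 62 were among the 84 that fell under it, where 0.54 were expected of unrelated lists. The 2 comparisons share no library. The whole set was lower under the antibody in 74 of 75 members (camera p = 3.29e-74, p = 0.00295 with an estimated correlation). Among the genes that rose under the antibody were Rnf187, from 21.4 ± 8.76 to 80.9 ± 23.8 CPM (log2 1.91 ± 0.24, adjusted p = 0.000467), Lsm4 (1.79 ± 0.26), Adssl1 (1.71 ± 0.28), Cers1 (1.63 ± 0.27), Fam174a (1.86 ± 0.33) and Podxl2 (1.69 ± 0.32). With the library factor as a covariate Lsm4, Adssl1, Fam174a and Podxl2 lay on the other side of 0 (-0.10, -0.60, -0.77 and -0.86), and 7 genes were called up and 41 down. In that fit fibro-adipogenic markers were higher (0.37, camera adjusted p = 0.0229). Of the 34 genes lower in trained DTR+ mice 19 were among these 74, where 0.22 were expected, and 15 of the 19 belong to the library factor, which scored -0.86 ± 0.28 with IgG and 0.01 ± 0.08 with the antibody. Slow fibre genes were lower in 13 of 14 members with 2 called and 10 over the list alone (camera adjusted p = 5.54e-05, adjusted p = 0.877 with an estimated correlation), macrophage markers in 21 of 23 with 1 called, dendritic and mast cell markers in all 6 and fibro-adipogenic markers in 15 of 17 with 1 called, and clock genes were higher in 14 of 18 (estimated-correlation adjusted p from 0.357 to 0.899). The called fibro-adipogenic marker was Ly6a, which is given above among interferon-induced genes. The marker of that list with the next smallest p, Tnxb, was not called (edgeR, adjusted p = 0.142). Ppargc1a stood at 50.8 ± 8.93 against 50.1 ± 3.46 CPM (0.02 ± 0.14).

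**Figure D4:**
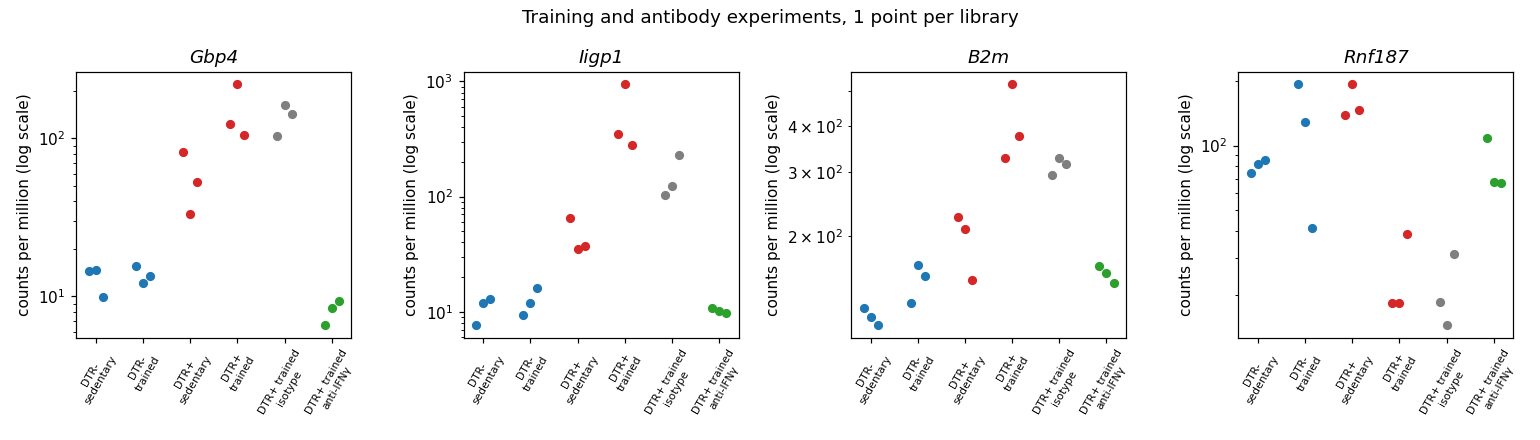
CPM on a log axis of Gbp4, Iigp1, B2m and Rnf187 in each library of the training and antibody experiments. Gbp4 averaged 13.1 and 13.8 CPM in DTR- groups, 55.9 and 150 CPM in sedentary and trained DTR+ mice, 137 CPM with isotype IgG and 8.11 CPM with anti-IFNγ.

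In mice of 24 months the same antibody tests whether IFNγ also drives interferon genes in aged resting muscle. With 2 mice per group edgeR and DESeq2 called 0 genes of 12531, and 64 had an unadjusted p under 0.05. Interferon-gamma response genes were lower in 32 of 35 members (median -0.79, camera adjusted p = 1.43e-09, adjusted p = 0.295 with an estimated correlation) and type I interferon genes in 21 of 24 (median -1.14, 1.87e-09, and 0.295 with an estimated correlation). Gbp9 stood at 0.631 ± 0.599 against 8.79 ± 2.06 CPM with IgG, Tgtp2 at 0.222 ± 0.127 against 4.56 ± 2.15 CPM, Gbp4 at 2.79 ± 2.03 against 18.1 ± 17 CPM and Rsad2 at 0.779 ± 1.1 against 15.1 ± 15.6 CPM (adjusted p = 1 for each). Of the genes higher in trained DTR+ mice 59 of 71 were lower under the antibody in aged mice (camera p = 3.66e-12, p = 0.0734 with an estimated correlation). The 4 libraries differed in content, from 3.25 to 14% of counts on mitochondrial genes. The log2 level of short against long transcripts ran from -2.42 to 1.86 within the antibody group. B2m stood at 187 and 22.55 CPM in the antibody libraries and at 120.7 and 203.6 CPM with IgG.

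The genes higher in trained DTR+ mice were followed in acute DTR+ against DTR- mice. At day 7 after exercise 74 of 77 were higher and 63 were called (camera p = 4.7e-24, p = 0.0588 with an estimated correlation), at day 1 57 of 77 were higher with 0 called by edgeR (p = 0.231 with an estimated correlation), and at rest 56 of 77 were higher with 15 called up and 3 down (p = 0.571 with an estimated correlation). The genes lower in trained DTR+ mice were higher in 29 of 34 members in the acute experiment at day 7 (camera p = 1.44e-05, p = 0.224 with an estimated correlation), and 20 of the 34 belong to the library factor. The quadriceps genes raised at day 1 in wild-type mice were higher in 43 of 55 members in trained DTR- muscle with 3 called (camera p = 3.62e-06, p = 0.0447 with an estimated correlation), and 44 of 57 were lower in DTR+ than DTR- mice at day 1 (p = 0.284 with an estimated correlation). The test of a different recovery in the 2 muscles called 7 genes, Fhl1 (adjusted p = 5.3e-05), Myh1, Ankrd2, Hspb6, Actn2, Lmcd1 and H19 (0.016).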

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

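The tests of the library factor in the genes lower in trained DTR+ mice, of its span in wild-type groups, of its slope in the interferon-gamma list within wild-type groups and of its part in the antibody result, and the splits that keep the muscles of an animal together, were chosen after those results were seen, as were 4 of the rules for reading a test, namely leaving chance open where the kinds of split differ, counting only genes shared with the uncorrected fit in the test of length and GC content, weighing the shared direction without sedentary DTR+ replicate 2 and reading the interferon-gamma list with the factor as covariate together with that slope.

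The 3 tests of a difference between groups each called genes and are given here for that reason. For the recovery response in quadriceps against tibialis anterior 7 genes were called. For the recovery response in DTR+ against DTR- mice 2610 were called in the acute experiment, and 34 for the training response in these genotypes.

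The calls between acute DTR+ and DTR- mice at rest and at day 7 moved with library content. With the trend on transcript length and GC content removed, 2631 genes were called at rest, 2054 of them among the 3794, and 2554 at day 7, 2003 of them among the 3608, so this trend is not their sole cause, and the interferon-gamma list at day 7 kept a median of 3.79 (camera adjusted p = 4.57e-19). The fold changes correlated across 9148 genes with the main axis of spread within the training groups at an absolute rho of 0.243 at rest and 0.346 at day 7, against 0.208 at day 1 where 0 genes were called by edgeR. At day 7 this reached the level set beforehand as a sign of a quality axis. At rest it did not, which leaves such an axis undecided there. Of 3730 called genes 64.3% had the same direction between resting DTR+ and DTR- mice of the training experiment, against 56.7% of all genes, but 46.9% of 3747 without sedentary DTR+ replicate 2, so an effect of Treg loss on these genes is undecided too. Genotype and library content cannot be separated at rest and at day 7 in these libraries. Library content also differed between day 1 and rest within each genotype. It therefore cannot be separated from exercise there, nor in the test of a different recovery by genotype.

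Genes lower in trained DTR+ than DTR- mice and higher under the antibody overlapped the library factor. Of those with a loading, 60.6% (20 of 33, with 0.38 expected) belong to its 100 genes. This fits a factor that also varies between wild-type libraries of one group. Its low scores did not extend to the other muscle of the same animal number. Number 13 scored -0.88 in quadriceps and 0.76 in tibialis anterior. Numbers 10 and 07 scored -0.95 and -0.80 in tibialis anterior, and 0.05 and 0.74 in quadriceps. Of the genes that were higher 0 of 50 belong to the 100 genes of the factor, but the 100 were taken from the positive end of the axis only. Trained DTR+ libraries scored low on it, so higher genes that follow the factor would lie at the other end. This 0 thus does not show the higher genes free of the factor. The largest span of the genes lower in trained DTR+ mice was 1.46 within a wild-type group. The difference between the trained groups was 1.47, so an effect of Treg loss or IFNγ cannot be told from that factor. With the factor as covariate these genes went from a median of -1.52 to -0.53 (median SE 0.296 and 0.369) with 0 called by edgeR, while the interferon-gamma list went from a median of 3.58 to 2.67 and its median SE from 0.427 to 0.609, which left 6 members called up, without a test of which of these changes ended the other calls. By the rule written beforehand, so few members still called counted as a sign of the factor. The slope of the list on the factor within wild-type groups, a test chosen later, gives a shift of 0.0702 in its mean (upper end of the 95% interval 0.179). Trained mice differed by 2.6. By this slope the factor gives a small part of that difference in the list, which argues against it as the main source. The slope was taken in wild-type mice only, and the count of calls with the covariate points the other way. How large a part the factor has in the trained difference therefore stays undecided. Under the antibody 23 of the interferon genes were called down with the covariate (median -3.17). There the score ran from -1.03 to -0.54 with IgG and from -0.04 to 0.10 with the antibody. The covariate thus nearly follows the treatment, so this fit cannot decide on the factor's part in that fall.

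Clock genes of opposed sets moved apart on average after exercise in wild-type mice. Arntl in quadriceps at day 1 kept -1.06 with the trend on length and GC content removed (adjusted p = 0.0273), so the trend does not account for it. The 8 genes set beforehand against Arntl, Npas2 and Clock were Per1, Per2, Per3, Dbp, Tef, Nr1d1, Nr1d2 and Ciart. At day 1 none of these 8 was called by edgeR in either muscle. Nr1d1 lay near 0 (log2 0.09 in quadriceps and -0.09 in tibialis anterior). The 8 had a mean of 0.79 and Arntl, Npas2 and Clock a mean of -0.85 at day 1 in quadriceps. In tibialis anterior these means were 0.83 and -0.75. Such opposite means fit a shift of the daily rhythm or of the hour of sampling. The hour is not given in the labels, so these cannot be separated.

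Each comparison of 3 against 3 mice was repeated over the 10 ways to split its libraries, which are too few for a share under 0.05. In quadriceps 1 split, the real one, reached the real count of 76, 39 and 28 at days 1, 2 and 7, and the highest other called 0. In tibialis anterior 1 split reached the real 7 and 8 at days 1 and 2 with 0 as the highest other, while at day 7 2 splits reached the real 2, the real one and one that called 4. In acute DTR- mice at day 1 against rest 1 split reached 2337, and the highest other called 0. For DTR+ against DTR- at day 1, where the real count was 0, all 10 splits reached it and 1 was the highest other. In the training experiment 1 split reached the real 13 in DTR-, 278 in DTR+, 6 between resting and 112 between trained genotypes, and with the antibody 1 split reached 158, each with 0 as the highest other. For the training response differing by genotype 4 of 100 splits reached the real 34, and the highest called 68, in splits that mix the genotypes. For the recovery response differing by muscle 6 of 100 splits reached the real 7, and the highest called 513, in splits that mix the muscles and part the animals. With the muscle labels swapped within animals 10 of 100 reached 7 and the highest called 674. Both kinds of split mix the muscles, so a steady difference between the muscles can pass as a difference in recovery. These counts therefore cannot decide on chance. With whole animals moved between days and the animal as block, 3 of 100 splits reached the real 10, and the highest called 19. Without the block 1 split, the real one, reached 7, and the highest other called 0. The first kind of split was the planned one and cannot decide on chance, and moving whole animals was chosen after it was seen, so chance stays open for these genes.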

How the results depend on the processing

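The length and GC correction, the library factor as covariate and the repeat without sedentary DTR+ replicate 2 were added after the data were seen. Named genes kept direction and side of the threshold in 996 of 1002 results with RLE factors, 887 of 968 with DESeq2, 965 of 967 without mitochondrially encoded genes, 882 of 1002 without a filter, 752 of 796 with the replicate block, 901 of 1001 with the length and GC correction and 190 of 288 with the covariate. Of list results 126 of 129 held with the block, 111 of 129 with the length and GC correction, 34 of 61 with the covariate and 57 of 166 with fry. Carried sets held in 16 of 16 results with 50 genes and in 8 of 16 with an estimated correlation. The sets of 34 and 19 lower genes are below the limit of 50, so their results could not change with it. Totals of 3359683 to 14445336 counts leave Foxp3 and Ifng near their floor. Where a count moved, the cause was not tested, except that leaving out a mouse or a group leaves fewer libraries.

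With DESeq2 the calls were 181, 147 and 115 in quadriceps and 86, 67 and 24 in tibialis anterior at days 1, 2 and 7. They were 63 in DTR- and 360 in DTR+ mice at day 7 against rest, 36 in DTR- and 547 in DTR+ mice for training, 28 between resting and 196 between trained genotypes, 31 for the muscle difference and 115 for the training difference. Without a filter they were 197, 178 and 167 in quadriceps, 143, 129 and 57 in tibialis anterior, 8 for acute DTR+ against DTR- at day 1, 146 and 367 at day 7 against rest in DTR- and DTR+, 45 and 511 for training in DTR- and DTR+, 47 and 260 between resting and trained genotypes, 375 with the antibody, 143 for the muscle and 147 for the training difference. RLE factors gave 4 calls at day 1 and 4 at day 7 in tibialis anterior, and leaving out mitochondrially encoded genes gave 4 at day 7.

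With only the compared groups in the fit the calls were 88 in quadriceps at day 7, 12 and 9 in tibialis anterior at days 1 and 7, 2028 for acute DTR+ against DTR- at day 7, 2 in DTR- and 1 in DTR+ at day 7 against rest, 60 and 91 for training in DTR- and DTR+, and 0 between resting genotypes of the training experiment by edgeR. With the replicate number as block 0 genes were called by edgeR in DTR- and 93 in DTR+ mice at day 7 against rest, 22 for the training difference and, with the animal as block, 10 for the muscle difference, and the block moved no other count by over 1.5 times. With the length and GC correction the calls were 3 in tibialis anterior at day 1, 4 in DTR- mice at day 7 against rest, 443 for training in DTR+ mice and 1581 for the acute difference. With the covariate they were 8 and 3 for training in DTR- and DTR+, 12 and 10 between resting and trained genotypes, 48 with the antibody and 1 for the training difference.

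With the covariate these lists turned direction, by camera adjusted p: for training in DTR+ mice complex I 0.178, complexes II to V 0.551, mitochondrially encoded mRNAs 0.206, mitochondrial ribosome 0.16 and matrix 0.16, between trained genotypes fatty acid oxidation 0.871, with the antibody fibro-adipogenic markers 0.0229, and for the training difference MHC 0.876, citrate cycle 0.399, fatty acid oxidation 0.358 and matrix 0.347. Genes that turned with it were Kcna7 0.0519, Tbx1 0.11 and Scand1 0.11 for training in DTR+ mice, and with the antibody Lsm4 -0.10, Adssl1 -0.60, Fam174a -0.77, Podxl2 -0.86, Mpped2 -0.28 and Rps2 -1.61. With the length and GC correction Des 0.10, Prdx3 -0.22, Col4a1 0.0886, B2m -0.51 and Pf4 -0.31 turned between resting acute genotypes, Des 0.00994 and Prdx3 -0.16 at day 7, and Prdx3 0.037 at day 1 against rest in DTR+ mice. The cause was not tested.

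Leaving out each library in turn moved 73 of 158 counts by over 1.5 times, and a group left with 1 mouse is assumed to vary like the others. In quadriceps the counts were 41 to 79 at day 1 (without day 1 replicate 16 48, sedentary 05 41 and 07 45), 13 to 35 at day 2 (without day 2 replicate 14 20, sedentary 05 15, 06 18 and 07 13) and 11 to 43 at day 7 (without day 7 replicate 08 43, 09 11 and 10 18, sedentary 05 14 and 07 14). In tibialis anterior they were 2 to 6 at day 1 (without day 1 replicate 16 3, 17 4 and 19 4, sedentary 06 2 and 07 3), 0 to 10 at day 2 (0 without day 2 replicate 15 and sedentary 05 or 07, 2 without 06) and 0 to 2 at day 7 (0 without day 7 replicate 08 or 09 and sedentary 05 or 06).

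In the acute experiment they were 2702 to 3708 between genotypes at rest, 0 to 0 at day 1 and 2429 to 3284 at day 7. At day 1 against rest they were 1330 to 2172 in DTR- (without day 1 replicate 2 1408 and 3 1330, sedentary 1 1350) and 4747 to 5341 in DTR+. At day 7 against rest they were 0 to 154 in DTR- (without day 7 replicate 1 0 and 3 154, sedentary 1 26, 2 0 and 3 2) and 76 to 346 in DTR+ (without day 7 replicate 2 346 and 3 76). The genotype difference had 1886 to 2945 and the muscle difference 6 to 23 (23 without tibialis anterior day 1 replicate 17).

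For training in DTR- mice the counts were 3 to 28 (without trained DTR- replicate 1 4 and 2 4, sedentary DTR- 1 3, 2 6 and 3 3, sedentary DTR+ 2 28) and in DTR+ 53 to 849 (without trained DTR+ replicate 1 167 and 2 53, sedentary DTR+ 2 849). Between resting genotypes they were 0 to 12 (0 without any sedentary DTR- replicate, and without sedentary DTR+ 1 1, 2 3 and 3 12). Between trained genotypes they were 47 to 239 (without trained DTR- replicate 1 61 and 2 63, trained DTR+ 2 47 and 3 239, sedentary DTR+ 2 191). The training difference had 2 to 149 (without trained DTR- replicate 1 2, 2 5 and 3 67, sedentary DTR- 1 4, 2 4 and 3 3, trained DTR+ 1 12, 2 11 and 3 149, sedentary DTR+ 2 56). With the antibody they were 73 to 382 (without antibody replicate 1 78, 2 80 and 3 96, IgG 2 73 and 3 382), and in aged mice 0 to 3 (without antibody replicate 1 3 and 3 2).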

Other observations

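Genes that fell in wild-type quadriceps at day 1 were followed in experiments that share no library with it, in comparisons chosen before the data were examined. These 19 genes were lower in 15 of 19 members at day 1 in DTR- mice, with 7 called (camera p = 0.000423, p = 0.0295 with an estimated correlation), and in 14 of 18 members in trained DTR- mice (p = 0.00345, and 0.0133 with an estimated correlation). The 34 genes lower in trained DTR+ mice were lower in 28 of 34 members under the antibody in aged mice (camera p = 0.00139, and 0.288 with an estimated correlation). Of these 34 genes 20 belong to the library factor. Their mean log2 level, relative to all libraries, was 0.906 and -0.251 with IgG and -0.891 and 0.266 with the antibody. The aged groups thus overlap, and this lean cannot be credited to the antibody.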
